A study of Homo sapiens with 12 samples.

How the data were processed

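Total RNA from KMS-11 cells was extracted with Trizol and converted to biotinylated cRNA with an Ambion MessageAmp kit made for Illumina arrays, per the labels. The series holds 12 arrays in 4 groups of 3: DMSO for 6 h, NSC12 for 6 h, DMSO for 12 h and NSC12 for 12 h. Groups, times, the 6 µM dose and replicate numbers were taken from the labels. The labels do not say whether the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

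The deposited values are probe intensities on a linear scale, from 69.5 to 25534, with 1 value per probe and array and no detection p-value. The scanner software, background correction and normalization used by the authors are not given in the sources used here. The arrays differed in mean intensity (from 347 to 634) and the lowest value of each array lay between 69.5 and 99.8, so the values were treated as unnormalized, with an additive background left in. This background understates the fold changes of dim genes. The highest value of each array lay between 13966 and 25534, and changes of genes near the top of the scale may be compressed, which was not tested. The number of arrays limits the precision.

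The table holds 47319 probes. The platform annotation gave 1 gene symbol for 30111 of them, several for 8 and listed none for 17200. Symbols were updated through the Entrez identifier in a table of RefSeq genes of GRCh38.p14, in which 30072 probes had a match; that table served for names and for finding which genes hold small nucleolar RNAs. The brightest probe over all arrays stood for each gene, which gave 20045 genes, 6691 of them with more than 1 probe. Where probes above background disagree for a named gene, this is stated beside the gene. Probes near background did not follow the brightest probe for ACACA, ATM, CDKN2B, CR2, FGF9, LSS, MCM7, MT1E, MT1H, OASL, SPRY1, ULK1 and XRCC2.

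A floor of 16 was set, and no value lay below it. Intensities were quantile normalized between arrays and taken to log2. No gene was removed for low signal. A background level of 6.98 (log2) was defined as the 95th percentile of the mean levels of 384 olfactory receptor genes, which few tissues outside the nose express, and 11229 genes (56.0%) lay above it. Where a gene lay below this level in 1 of the groups compared, the fold is given as a bound against that level.

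Each gene was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group and moderated variances with an intensity trend, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. The contrasts were NSC12 against DMSO at 6 h, the same at 12 h, the difference between these (12 h minus 6 h) and DMSO at 12 h against DMSO at 6 h. Changes are log2 differences with the standard error (SE) of the fit; group levels are means ± SD of 3 arrays. Figures were drawn with matplotlib 3.10.9.

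A total of 32 gene lists were written before the data were examined, as were the tests and most alternatives. Lists were compared with all other genes by camera, limma's competitive test, with a preset correlation of 0.01 and adjustment over 96 tests (32 lists and 3 contrasts). The lists of the DMSO contrast were adjusted among themselves. A test with the correlation estimated from the residuals and fry, limma's self-contained rotation test, were run as well. Of 22 calls with the preset correlation, 5 held with an estimated correlation: metallothioneins and heat shock genes at 6 h and at 12 h, and heat shock genes for the difference between the times. The words "adjusted over the list alone" refer to p-values adjusted among the members of a list.

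Named genes follow a rule set before the data were examined. It takes the 8 largest rises and falls at 6 h and at 12 h, and the 5 largest each way for the difference between the times, among genes past the threshold, above background in a compared group and with no overlap between the arrays compared. For the difference between times, no overlap was required at 6 h or at 12 h. Immunoglobulin genes and genes without an official name were excepted, and symbols withheld from the text are left out without replacement. Up to 4 members of each described list with the largest changes are added, or up to 2 of the highest level where none passed, and MYC, FGFR3, NSD2, FGFR1, CCND1, CCND2, HMOX1, MCL1 and IRF4 whatever their values. Which lists are described at length, and how many members, was chosen after the values were seen. Outside the rule, and chosen after their values were seen, are the 5 largest changes each way over time in DMSO, HSPE1, ELOVL1, HSPB1, GINS2, BNIP3, DNAJB9, H2AC20, H1-2, RNU6-1 and SRSF1.

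The analysis was tested on simulated data over 20045 genes with each gene's mean over the arrays and its fitted spread. Changes were planted only in genes above background, with independent noise between genes on values already normalized. The shares called therefore do not cover dim genes, normalization or correlated genes. For log2 changes of 0.25, 0.5, 1 and 2, the share called was 26%, 98%, 100% and 100% at 6 h, 31%, 96%, 100% and 100% at 12 h, and 4%, 54%, 100% and 100% for the difference between the times. Unchanged genes called numbered 11, 18 and 6 in these contrasts, and 0 genes were called over time in DMSO, where none was changed.

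Alternatives covered the scaling (median centring), the filter on dim genes, the treatment of several probes per gene, an added constant of 100, the variance model, array weights, a 2-fold minimum, fits on 6 arrays, an unmoderated test, the replicate number as a block and leaving out each array. Background correction by normexp with an offset of 50, cyclic loess, array brightness as a covariate and leaving out the dimmest array of each DMSO group were added after the data were seen. Array medians lay between 101.1 and 137.2 in intensity, near the background level of 126.5, so median centring mostly aligns background. It leaves differences in brightness among bright genes, and calls lost under it may reflect these differences. List calls were not tested again under median centring, and only list medians are given there. No chip, slide or scan information was available to test as a batch. Array positions and the sequences of probes were not used here.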

Results

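Transcript levels were measured in KMS-11, an established human multiple myeloma line whose chromosomal translocation joins the FGFR3 and NSD2 region to the immunoglobulin heavy chain locus. Cells kept in 1% FBS for 24 h were given DMSO or 6 µM NSC12, a small molecule described as a trap for fibroblast growth factors (FGFs), for 6 h or 12 h. Each of the 4 groups held 3 arrays. Mean intensity per array ranged from 347 (DMSO 6 h, replicate 3) to 634 (DMSO 6 h, replicate 2). The group means of array brightness were 522 ± 153 (SD, n = 3) in DMSO and 428 ± 61.6 in NSC12 at 6 h, and 538 ± 77.3 and 588 ± 36.1 at 12 h. Between arrays of a group, log2 values correlated at 0.992 to 0.996, and the lowest correlation between any pair of arrays was 0.967. No pair of arrays held identical values.

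The first question was what NSC12 changed within 6 h. HSPA6, a heat shock protein of the HSP70 family that is nearly silent without stress, went from 8.27 ± 0.06 in DMSO to 13.96 ± 0.03 in NSC12 (log2, SD, n = 3), 51.7-fold (log2 change 5.69 ± 0.07 SE, adjusted p = 1.07e-23). MT1G, a metallothionein that binds zinc and copper, rose 43.8-fold, and CCL3, a chemokine, rose 37.7-fold. The U1 small nuclear RNAs RNVU1-7, RNU1-3 and RNVU1-18 rose 42.0-fold, 41.8-fold and 34.5-fold. HSPA7 (75.2-fold) and CCL3L1 (37.2-fold) completed the 8 largest rises; HSPA6 with HSPA7, CCL3 with CCL3L1, the MT1 genes and the U1 RNAs are near-identical families whose probes may share signal, so each member is uncertain.

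The largest falls at 6 h were of MIAT, a long noncoding RNA (log2 change -2.22 ± 0.08), and ZC3HAV1, an antiviral zinc finger protein (-2.07 ± 0.08), although the other probes of ZC3HAV1 gave 0.28 and 0.44. SKP2, the substrate receptor of a ubiquitin ligase that targets CDKN1B, was 2.82-fold lower, and all its probes fell (-0.93 as their mean). TXNIP, an inhibitor of thioredoxin, fell by 1.42, and TRA2B, a splicing regulator, by 1.43. The small RNAs SNORA61, SNAR-A1 and SNORD104 fell by 1.74, 1.71 and 1.55.

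Metallothioneins and their zinc-responsive companions rose together at 6 h: 7 of 9 measured members rose and none fell (9 rose adjusted over the list alone). MT2A rose from 8.01 ± 0.14 to 12.02 ± 0.14 (log2, SD, n = 3), MT1E rose 7.23-fold, and MT1H at least 9.23-fold from a level below background. The list stood above other genes (median log2 change 2.70, and 1.74 as the mean of probes; adjusted p = 3.11e-26 with the preset correlation and adjusted p = 0.00101 with an estimated correlation). Of 16 heat shock genes, 10 rose and none fell, a count that was the same adjusted over the list alone. DNAJB1, a co-chaperone, rose by 3.81 on the log2 scale, HSPA1B rose 6.03-fold, BAG3 3.55-fold and HSPA1A at least 2.13-fold. The list median was 0.32 (adjusted p = 1.11e-15, and adjusted p = 0.0032 with an estimated correlation).

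**Figure D1:**
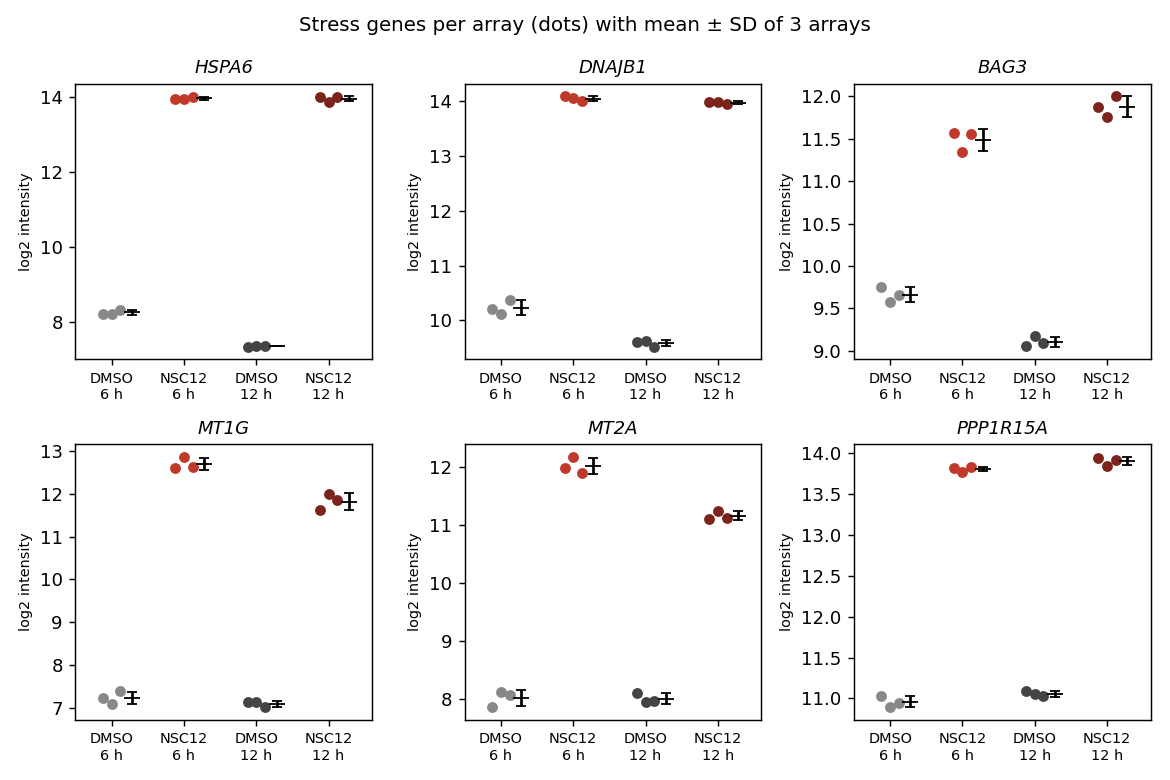
Levels of 6 stress genes on each array (vertical axis, log2 intensity after quantile normalization) in the 4 groups (horizontal axis); dots are arrays and bars are the mean ± SD of 3 arrays. The 3 NSC12 arrays lay above the 3 DMSO arrays of the same time for each gene, with HSPA6 near 14 in NSC12 and below 8.4 in DMSO, and the vertical axes do not start at 0.

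Among 28 genes of the ATF4 stress response, 6 rose and 7 fell at 6 h (8 and 8 adjusted over the list alone). PPP1R15A, which directs removal of the phosphate from eIF2alpha, rose 7.21-fold, ATF3 4.65-fold and DDIT3 3.87-fold, all transcripts known to rise under stress; the other probes of ATF3 lay near background and did not pass, and their mean with the brightest was 0.77. The list as a whole was not called (adjusted p = 0.179); its median was -0.01 (-0.09 under median centring) and its mean 0.24. Of 20 NRF2 targets, which include antioxidant enzymes, ABCB6 alone passed (-0.76; 1 fell adjusted over the list alone; list adjusted p = 0.944, with a median of 0.03, -0.06 under median centring, and a mean of -0.003). HMOX1, which degrades heme, did not pass (0.18 ± 0.09, adjusted p = 0.241).

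Of 12 fatty acid synthesis genes, 5 fell and none rose at 6 h (the same adjusted over the list alone), among them FASN (-0.72), ACACA (-0.45) and ACLY (-0.36); ACLY lost its call under median centring with a change of -0.43 (adjusted p = 0.142). The list was lower (median -0.09, and -0.21 under median centring; adjusted p = 0.0239), and this call was lost with an estimated correlation (adjusted p = 0.309), among genes above background (0.106) and without the dimmest array of each DMSO group (adjusted p = 0.0538). Of 19 cholesterol synthesis genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone). LSS, lanosterol synthase, changed by -1.13 (-0.40 as the mean of probes) and HMGCS1 by 0.60, the latter at 0.44 and not past the threshold under median centring (adjusted p = 0.141). The list was not called (adjusted p = 0.229), and its median of 0.11 became -0.01 under median centring.

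FGF and MAPK response genes did not fall as a list at 6 h (adjusted p = 0.213). The list holds genes induced through FGF receptor and MAPK signalling, including its feedback inhibitors. Of 21 genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone). EGR1 rose by 0.73 and IL17RD, an inhibitor of FGF signalling, fell by 0.85, the latter on 1 probe of 3, the only probe above background. FGFR3 was at 13.92 ± 0.04 in DMSO and 13.91 ± 0.08 in NSC12 (change -0.01 ± 0.06, adjusted p = 0.952). This level lay near the top of the scale, where a change may be compressed. FGFR1 and CCND1 lay below background in both groups. NSD2 was dim on its brightest probe (7.48 ± 0.01 and 7.58 ± 0.07) and did not pass (0.09 ± 0.08, adjusted p = 0.559).

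MYC was higher at 6 h (0.34 ± 0.08, adjusted p = 0.00338) and IRF4, a factor of plasma cell identity, was higher by 0.33; both calls were lost under median centring, MYC with a change of 0.36 (adjusted p = 0.187) and IRF4 with 0.18 (adjusted p = 0.74). CCND2, the D-type cyclin of this line, fell by 0.37, also lost under median centring at -0.37 (adjusted p = 0.142). Of 31 genes activated by MYC, 1 rose and 6 fell (3 and 8 adjusted over the list alone), with TFB2M at -1.13 and CAD at -0.84 (list adjusted p = 0.145). Of 44 ribosomal protein genes, 5 rose and none fell (3 adjusted over the list alone), with RPL13 at 0.64, on 1 probe of 2 (the other 0.03), and RPS9 at 0.31. Both calls ended under median centring, RPL13 at 0.45 (adjusted p = 0.121) and RPS9 at 0.35 (adjusted p = 0.173). The list was called (adjusted p = 0.0343), and lost with an estimated correlation (adjusted p = 0.109), among genes above background (0.106), with cyclic loess (0.0721), without the dimmest array of each DMSO group (0.0888) and without DMSO 6 h replicate 3 (0.0837), NSC12 6 h replicate 1 (0.0539) or NSC12 6 h replicate 2 (0.0631).

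Of 9 genes that restrain apoptosis, CFLAR (-0.69) and MCL1 (-0.32) fell and none rose (3 fell adjusted over the list alone; list adjusted p = 0.112). CFLAR did not pass without DMSO 6 h replicate 1 (adjusted p = 0.124), DMSO 6 h replicate 2 (0.0528), NSC12 6 h replicate 1 (0.0552) or NSC12 6 h replicate 3 (0.0892), nor with array brightness as a covariate (0.0635). MCL1 did not pass without DMSO 6 h replicate 2 (adjusted p = 0.0817) or NSC12 6 h replicate 3 (0.118), under median centring (-0.46, adjusted p = 0.123) or as the mean of its probes (-0.08, adjusted p = 0.658), the second probe being at 0.17. PMAIP1, which promotes apoptosis, rose by 0.41 (adjusted p = 0.00444), a call lost under median centring at 0.25 (adjusted p = 0.572); of 17 genes promoting apoptosis 1 rose and 2 fell (2 and 2 adjusted over the list alone).

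By limma, 2619 of 20045 genes changed at 6 h, 1114 higher and 1505 lower, of which 80 and 38 by at least 2-fold; 4746 had an unadjusted p under 0.05. Under median centring the split was 275 higher and 1194 lower (18.7% higher in place of 42.5%). That setting leaves differences in brightness among bright genes, and the group means of brightness at 6 h were 428 ± 61.6 in NSC12 and 522 ± 153 in DMSO. The arrays of NSC12 and DMSO did not overlap for 27.9% of genes, where chance gives 10%.

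The same comparison at 12 h asked how far the response had gone. HSPA6 reached 13.95 ± 0.07 against 7.36 ± 0.01 in DMSO (log2, SD, n = 3), a log2 change of 6.58 ± 0.07 SE (adjusted p = 5.07e-25), and HSPA7 rose 91.1-fold. The U1 RNAs RNVU1-7, RNU1-3, RNVU1-18 and RNU1-1 rose 34.2-fold, 33.2-fold, 26.3-fold and 23.8-fold, MT1G rose 26.2-fold and DNAJB1 20.8-fold. MIAT fell by 3.02 and ZC3HAV1 by 2.00, the latter again on 1 probe, with the others at 0.09 and 0.55. The other large falls were of HNRNPA0, an RNA-binding protein (-1.96), SUN2, of the nuclear envelope (-1.94), MEF2D, a transcription factor (-1.69), XPOT, which exports tRNA (-1.69), PGAM1, of glycolysis (-1.67), and MAT2A, which makes S-adenosylmethionine (-1.63).

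Heat shock genes rose further in number at 12 h: 13 of 16 rose and 1 fell (the same adjusted over the list alone), with HSPA1B 9.11-fold, BAG3 6.81-fold and HSPA1A at least 6.00-fold higher. HSPE1, a mitochondrial chaperonin, was the member that fell (-0.39), but not under median centring (-0.15, adjusted p = 0.612) or without NSC12 12 h replicate 2 (0.0605), and the mean of its probes gave 0.16. Of 9 metallothionein genes, 7 rose and none fell (the same adjusted over the list alone), with MT2A 8.90-fold, MT1H at least 4.90-fold and SLC30A1, a zinc exporter, 6.11-fold higher. Both lists gave adjusted p = 7.32e-13, and adjusted p = 0.00363 with an estimated correlation. PPP1R15A (7.20-fold), ATF3 (4.89-fold) and DDIT3 (3.27-fold) stayed high in the ATF4 list, in which 12 of 28 rose and 10 fell (the same adjusted over the list alone). SLC7A5, an amino acid transporter, was among those that fell (-1.15; list adjusted p = 0.242).

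Of 27 genes of DNA replication, 13 fell and 3 rose at 12 h (13 and 4 adjusted over the list alone). UHRF1 (-1.30), RRM2 (-1.19), E2F2 (-1.17) and MCM7 (-0.90), which act in DNA methylation upkeep, nucleotide supply, S phase entry and origin licensing, led the list (median -0.12, adjusted p = 0.0219). As the mean of probes UHRF1 was at -0.80 and MCM7 at -0.52. Of 25 mitotic genes, 10 were higher and 3 lower (the same adjusted over the list alone), led by CENPE (0.81), DLGAP5 (0.61) and TTK (0.61; list adjusted p = 0.0407). With an estimated correlation both calls were lost (adjusted p = 0.109 and adjusted p = 0.239), as they were among genes above background (adjusted p = 0.106 and adjusted p = 0.147). The mitotic call also ended with cyclic loess (adjusted p = 0.0623), with array brightness as a covariate (0.0506), without the dimmest array of each DMSO group (0.0538) and without DMSO 12 h replicate 1 (0.054), DMSO 12 h replicate 2 (0.0652) or NSC12 12 h replicate 3 (0.0857).

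Some survival genes were lower at 12 h. Of 9 genes restraining apoptosis, 5 fell and none rose (the same adjusted over the list alone): BCL2 fell from 11.06 ± 0.11 to 10.17 ± 0.09 (-0.88 ± 0.07), BIRC5 by 0.60 and MCL1 by 0.56, the brightest probes of BCL2 falling and its probes near background not passing. The list gave adjusted p = 0.0269, and adjusted p = 0.162 with an estimated correlation and 0.0975 among genes above background. Of 17 genes promoting apoptosis, 6 rose and 5 fell (9 and 5 adjusted over the list alone), with PMAIP1 at 0.91 and HRK at 0.81 (list adjusted p = 0.304). CCND2 fell by 0.79 (0.51 under median centring), IRF4 by 0.40 and MYC by 0.59 ± 0.08 (adjusted p = 2.72e-06). As the mean of probes BCL2 was at -0.42 and MYC at -0.36. The second MYC probe did not pass (-0.14, adjusted p = 0.443), and MYC and IRF4 lost their calls under median centring, at -0.33 (adjusted p = 0.137) and -0.39 (adjusted p = 0.138).

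Of 17 plasma cell genes, 8 fell and none rose at 12 h (8 fell and 1 rose adjusted over the list alone; list adjusted p = 0.0414, and adjusted p = 0.309 with an estimated correlation). PRDM1, the factor that drives plasma cell differentiation, fell by 0.98 on its brightest probe, while its other probes gave -0.57, 0.38 and 0.67, and the mean of probes did not pass (adjusted p = 0.244). SDC1, the plasma cell surface marker CD138, fell by 0.49 but not as the mean of its probes (adjusted p = 0.266). The list call ended as the mean of probes (median -0.09, adjusted p = 0.171), among genes above background (0.195), with cyclic loess (0.0768), with array brightness as a covariate (0.0506) and without the dimmest array of each DMSO group (0.0593). It also ended without DMSO 12 h replicate 1 (0.0581), DMSO 12 h replicate 2 (0.0818), NSC12 12 h replicate 1 (0.0705), NSC12 12 h replicate 3 (0.0501) or NSC12 6 h replicate 2 (0.0515), which enters through the shared variance and the adjustment.

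**Figure D2:**
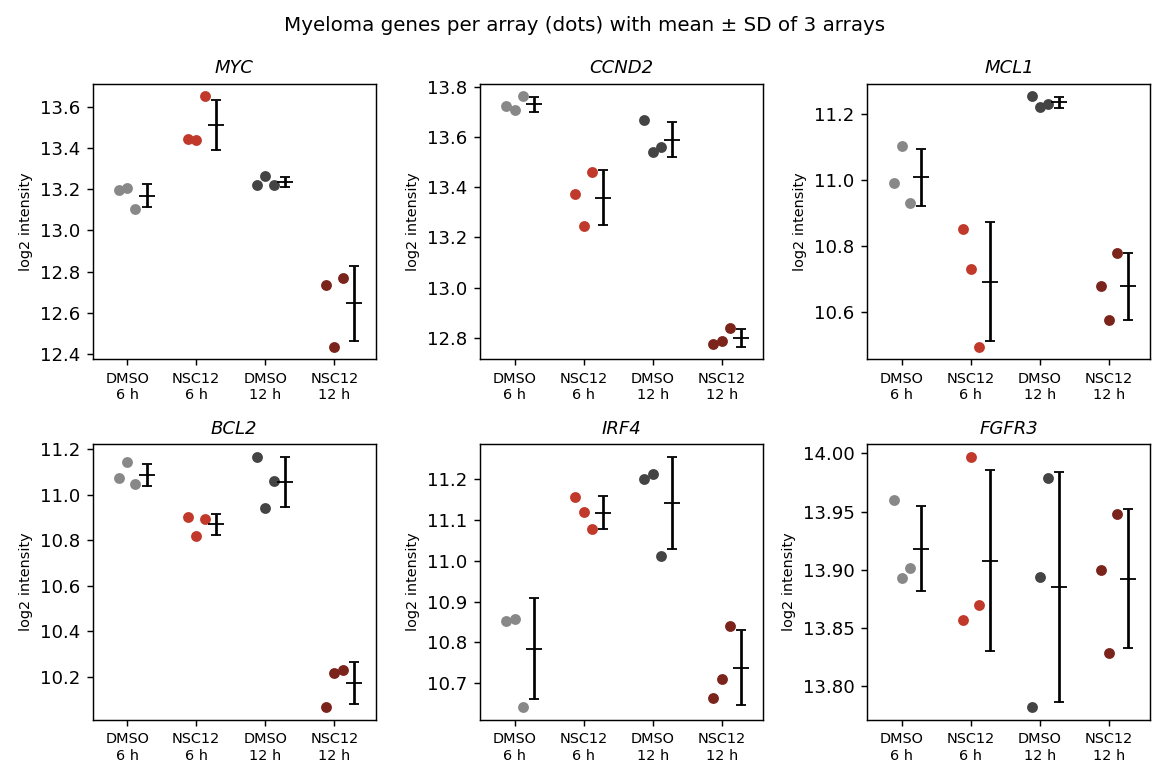
Levels of 6 genes of myeloma biology on each array (vertical axis, log2 intensity after quantile normalization, not starting at 0) in the 4 groups (horizontal axis); dots are arrays and bars are the mean ± SD of 3 arrays. FGFR3 stayed near 13.9 in all groups, close to the top of the scale, where a change may be compressed. BCL2 and CCND2 were lowest in NSC12 at 12 h.

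In lipid metabolism, SCD (-1.10) and ACLY (-1.10) fell and FASN was 2.82-fold lower at 12 h, with 5 of 12 fatty acid synthesis genes lower and 1 higher, the same adjusted over the list alone. The riser was ELOVL1 (0.39), a call lost under median centring at 0.25 (adjusted p = 0.251). The list was called (adjusted p = 0.0309), and lost with an estimated correlation (adjusted p = 0.321), among genes above background (0.0975), without the dimmest array of each DMSO group (0.0706) and without DMSO 12 h replicate 1 (0.0595). Of 19 cholesterol synthesis genes, 3 rose and 6 fell (4 and 7 adjusted over the list alone), with LSS at -1.60 (-0.69 as the mean of probes), SQLE, squalene epoxidase, at -0.86 and CYP51A1 at 0.68. That list was not called (adjusted p = 0.54), its median (0.04) and mean (-0.14) differed in sign, and its median was -0.07 under median centring.

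FGF and MAPK response genes showed 5 falls and no rise among 21 at 12 h, the same adjusted over the list alone (list adjusted p = 0.213). SPRY1, a feedback inhibitor of FGF signalling, fell by 1.06 (0.60 as the mean of probes) and EGR1, an immediate early gene, by 0.66. FGFR3 did not pass (0.01 ± 0.06, adjusted p = 0.959), nor did NSD2 (0.10 ± 0.08, adjusted p = 0.437). FGFR1 and CCND1 lay below background in both groups. Of 31 genes activated by MYC, 14 fell and 6 rose (16 and 7 adjusted over the list alone), with TFB2M at -1.38 and CAD at -0.79 (list adjusted p = 0.161).

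Of 22 interferon response genes, 8 rose and none fell at 12 h (9 rose adjusted over the list alone), with IFI6 2.00-fold, IFIT2 1.76-fold and OASL 1.46-fold higher. The list gave adjusted p = 0.0238, and adjusted p = 0.207 with an estimated correlation and 0.0975 among genes above background. Of 20 NRF2 targets, 5 rose and 5 fell (5 and 6 adjusted over the list alone). HMOX1 rose 1.42-fold, whereas TXNRD1, thioredoxin reductase, fell by 0.90 (list adjusted p = 0.986). Of 20 endoplasmic reticulum chaperone genes, 8 fell and 3 rose (10 and 3 adjusted over the list alone), with PDIA6 at -0.97 and CRELD2 at -0.70 (list adjusted p = 0.0697). Of 38 oxidative phosphorylation genes, 11 rose and 5 fell (12 and 6 adjusted over the list alone), with SDHA at -0.95 and ATP5F1A at -0.86 (list adjusted p = 0.161).

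Markers of other cell types gave little signal: 2 of 13 T and NK cell genes, 2 of 12 myeloid genes and 4 of 12 stromal and endothelial genes lay above background. At 6 h no marker of these lists or of the B cell list changed. At 12 h LCK (0.21) and DCN (0.32) passed upward and PDGFRB (-0.30) downward, and no myeloid marker passed (adjusted over the list alone, no T and NK cell marker, DCN up and PDGFRB down). The lists gave adjusted p = 0.661 (T and NK), 0.978 (myeloid; median 0.003, -0.003 under median centring, mean -0.01) and 0.986 (stroma; median -0.02 and mean -0.001, the test pointing up). The LCK call ended without DMSO 12 h replicate 1 (adjusted p = 0.0516), DMSO 12 h replicate 3 (0.0706), NSC12 12 h replicate 2 (0.0541) or NSC12 12 h replicate 3 (0.0524), without the dimmest array of each DMSO group (0.0517), under median centring (0.18, adjusted p = 0.122) and as the mean of probes (0.06, adjusted p = 0.393); DCN did not pass as the mean of probes (0.377). Of 10 B cell genes, 1 rose and 3 fell at 12 h (the same adjusted over the list alone), list adjusted p = 0.735, led by CR2 (-0.51) and BACH2 (-0.43), the second probe of BACH2 being at -0.17.

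**Figure D3:**
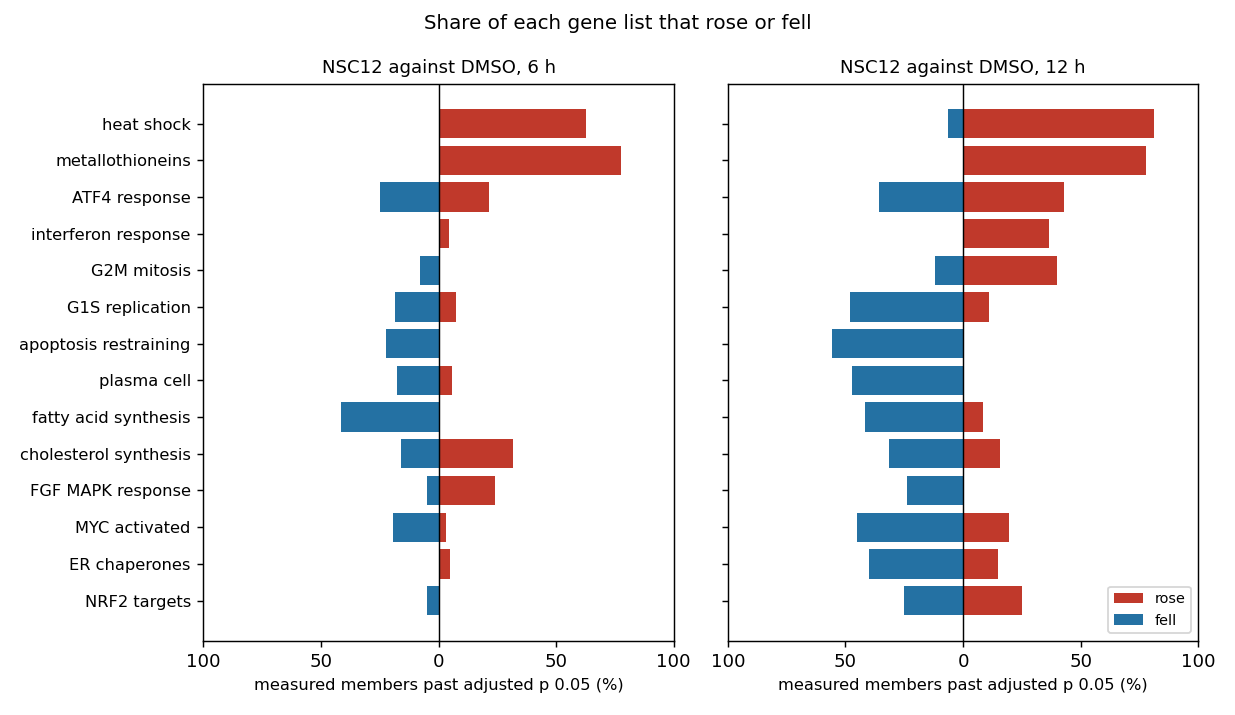
Share of the measured members of 14 gene lists that rose (red, right) or fell (blue, left) past an adjusted p of 0.05 (horizontal axis, percent) for NSC12 against DMSO at 6 h and 12 h. Heat shock genes and metallothioneins reached the largest rising shares, 10 of 16 and 7 of 9 at 6 h. Most other lists had members on both sides at 12 h, and fewer did at 6 h.

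At 12 h, 5784 of 20045 genes changed by limma, 2734 higher and 3050 lower, of which 142 and 193 by at least 2-fold; 7132 had an unadjusted p under 0.05. Under median centring the split was 1484 higher and 2605 lower (36.3% higher in place of 47.3%). Groups did not overlap for 38.2% of genes, against 10% by chance. Of the genes higher at 6 h, 821 (73.7%) were also higher at 12 h, where independent lists over all 20045 genes would share 151.9. Of those lower at 6 h, 1157 (76.9%) were also lower, against 229. The comparisons share no array, but they share an estimate of each gene's spread, which favours calls of the same genes. Of the calls, 2530 at 6 h and 5627 at 12 h lay above background. Both points make the expected counts too low. Another 25 genes went from higher to lower and 34 from lower to higher. Across the 11229 genes above background, which are not independent replicates, the changes correlated with r = 0.756 and rho = 0.645.

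The difference between the responses at 12 h and 6 h was tested directly. RIMBP3 had the largest gain (2.06 ± 0.15), on 1 probe of 3, the others being near background (0.79 as the mean of probes). RN7SK, the RNA that restrains transcription elongation, gained 1.77, ID1, an inhibitor of differentiation factors, 1.61, HSPA1A 1.52, on DMSO levels below background, and TRA2A, a splicing regulator that changed by -1.38 at 6 h and did not pass at 12 h (0.13), 1.51. The largest losses were of the small nucleolar RNA SNORD14C (-1.48), RRM2 (-1.43), XPOT (-1.41), EGR1 (-1.39) and PSMC4, a proteasome ATPase (-1.25). EGR1 was above DMSO at 6 h and below it at 12 h. The differences were -0.93 ± 0.11 for MYC (adjusted p = 1.26e-05), -0.74 for IRF4 and -0.42 for CCND2, and these 3 calls ended under median centring, at -0.69 (adjusted p = 0.0815), -0.56 (adjusted p = 0.331) and -0.14 (adjusted p = 0.858). MCL1 did not pass (-0.24, adjusted p = 0.246; as the mean of probes -0.53, adjusted p = 0.00659). HMOX1 (0.32, adjusted p = 0.13), FGFR3 (0.02, adjusted p = 0.946), NSD2 (0.01, adjusted p = 0.985), FGFR1 (0.02, adjusted p = 0.935) and CCND1 (-0.11, adjusted p = 0.575) did not pass either.

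In what follows, gained and lost describe NSC12 relative to DMSO at 12 h against 6 h, and either arm can have moved. Heat shock genes gained (9 of 16 up and 1 down, 10 and 1 adjusted over the list alone; median 0.34, adjusted p = 5.2e-07, and adjusted p = 0.0217 with an estimated correlation), with BAG3 at 0.94. HSPA1A (1.52) and CRYAB (0.65) lay below background in DMSO at both times, and with these levels raised to background their differences were 1.49 and 0.61. HSPB1 was the member that lost (-0.33), a call not kept under median centring (-0.11, adjusted p = 0.887) or without the dimmest array of each DMSO group (-0.26, adjusted p = 0.0624). Between 6 h and 12 h the median of the heat shock list was -0.24 in DMSO (95% bootstrap interval over genes -0.343 to -0.0421) and 0.03 in NSC12 (-0.0775 to 0.149). Metallothioneins lost (5 of 9 down and none up, the same adjusted over the list alone; median -0.64, adjusted p = 0.000105, and adjusted p = 0.0565 with an estimated correlation), with MT2A at -0.85 and MT1G at -0.74. MT1H (-0.92) lay below background in DMSO at both times, and with these levels raised to background its difference was -0.91. The list median was -0.68 in NSC12 arrays and -0.01 in DMSO arrays between the times, and the difference was -0.37 under median centring and -0.30 as the mean of probes. MT2A and MT1G did not pass under median centring (-0.61, adjusted p = 0.229, and -0.43, adjusted p = 0.496), nor MT1G with cyclic loess (adjusted p = 0.0762).

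Replication genes lost (7 of 27 down and GINS2 up by 0.61; 10 and 1 adjusted over the list alone; adjusted p = 0.00417, and adjusted p = 0.0565 with an estimated correlation), with RRM2 and UHRF1 (-0.93, and -0.58 as the mean of probes) in front. Mitotic genes gained (6 of 25 up, none down, the same adjusted over the list alone; adjusted p = 0.00611, and adjusted p = 0.112 with an estimated correlation), with CENPE at 1.02 and HMMR at 0.62. Under median centring the replication median was -0.02 in place of -0.16 and the mitosis median 0.30 in place of 0.10. UHRF1 (-0.82, adjusted p = 0.0722), GINS2 (0.73, adjusted p = 0.116) and HMMR (0.73, adjusted p = 0.119) did not pass. Between the times the replication median moved by -0.005 in NSC12 arrays and 0.02 in DMSO arrays, and the mitosis median by 0.05 and -0.05. FGF and MAPK response genes lost (5 of 21 down, IL17RD up by 0.61, the same adjusted over the list alone). Their list gave adjusted p = 0.0111, and adjusted p = 0.109 with an estimated correlation and 0.0975 among genes above background. SPRY1 was at -0.92 (-0.49 as the mean of probes), not past the threshold under median centring (-0.80, adjusted p = 0.0825). The median of this list moved by -0.06 in NSC12 arrays and rose by 0.09 in DMSO arrays between the times. Endoplasmic reticulum chaperones lost (7 of 20 down and 1 up, 8 and 1 adjusted over the list alone; adjusted p = 0.00652, and adjusted p = 0.112 with an estimated correlation), with PDIA6 at -0.83 and EDEM1 at -0.53, both not past the threshold under median centring (-0.71, adjusted p = 0.152, and -0.50, adjusted p = 0.265). The list median moved by -0.01 in NSC12 arrays and 0.09 in DMSO arrays, and the difference of -0.14 was -0.06 under median centring. DNAJB9, an endoplasmic reticulum co-chaperone, was the member that gained (0.38, adjusted p = 0.0282). Its call ended under median centring (0.55, adjusted p = 0.339), without the dimmest array of each DMSO group (0.32, adjusted p = 0.0975) and without DMSO 6 h replicate 3 (0.0561), NSC12 6 h replicate 1 (0.0518), 2 (0.0643) or 3 (0.0535), DMSO 12 h replicate 1 (0.0594), or NSC12 12 h replicate 2 (0.0819) or 3 (0.0942).

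Of 22 interferon response genes 4 gained and none lost (5 gained adjusted over the list alone; adjusted p = 0.0239, and adjusted p = 0.211 with an estimated correlation), led by IFI6 (1.00) and IFIT2 (0.55), with a median of 0.05 in NSC12 arrays and -0.03 in DMSO arrays between the times. The interferon list call ended among genes above background (adjusted p = 0.0975), with array brightness as a covariate (0.0781) and without NSC12 6 h replicate 2 (0.0515). Cholesterol synthesis genes lost (5 of 19 down and 2 up, the same adjusted over the list alone; adjusted p = 0.0309, and adjusted p = 0.309 with an estimated correlation), with SQLE at -1.08 and INSIG1 at -0.98, the latter not past the threshold under median centring (-0.72, adjusted p = 0.0824). Between the times the cholesterol median moved by -0.03 in NSC12 arrays and 0.20 in DMSO arrays, and the difference of -0.11 was -0.06 under median centring. That list call ended among genes above background (adjusted p = 0.152), without the dimmest array of each DMSO group (0.0974) and without DMSO 12 h replicate 1 (0.083), DMSO 6 h replicate 1 (0.0619) or NSC12 6 h replicate 2 (0.0851). Hypoxia and glycolysis genes lost (8 of 23 down and 1 up, the same adjusted over the list alone; adjusted p = 0.0239, and adjusted p = 0.109 with an estimated correlation), with PFKFB3 at -0.80 and HK2 at -0.68 (-0.36 and -0.44 as the mean of probes). Under median centring the list median was 0.01 in place of -0.10, and PFKFB3 (-0.76, adjusted p = 0.0837) and HK2 (-0.66, adjusted p = 0.173) did not pass. The hypoxia list call ended as the mean of probes (median -0.05, adjusted p = 0.107), among genes above background (0.106) and without the dimmest array of each DMSO group (0.0538). The hypoxia median moved by -0.05 in NSC12 arrays and 0.03 in DMSO arrays. BNIP3, of mitochondrial turnover, was the member that gained (0.36, adjusted p = 0.0307), a call that ended under median centring (0.44, adjusted p = 0.449), with array brightness as a covariate (0.32, adjusted p = 0.0767) and without DMSO 6 h replicate 1 (0.0627) or 2 (0.0801), NSC12 6 h replicate 1 (0.0593), 2 (0.0558) or 3 (0.0627), DMSO 12 h replicate 1 (0.0637) or 2 (0.0661), or NSC12 12 h replicate 2 (0.0896). Genes that MYC represses lost (2 of 10 down, none up; 3 down adjusted over the list alone; adjusted p = 0.0323, and adjusted p = 0.148 with an estimated correlation), with NDRG1 at -0.96 and CDKN1B at -0.58, the latter not past the threshold under median centring (-0.43, adjusted p = 0.52) or as the mean of probes (-0.23, adjusted p = 0.161). Their median moved by -0.07 in NSC12 arrays and 0.07 in DMSO arrays. The call of this list ended as the mean of probes (median -0.15, adjusted p = 0.16), among genes above background (0.106), with array weights (0.0548), with array brightness as a covariate (0.0549) and without the dimmest array of each DMSO group (0.0689). It also ended without DMSO 12 h replicate 1 (0.0602) or NSC12 6 h replicate 2 (0.057).

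In all, limma called 2089 genes with a response that differed between the times, 933 higher and 1156 lower at 12 h than at 6 h, of which 37 and 28 by at least 2-fold. Under median centring 363 were called, 277 higher and 86 lower (76.3% higher in place of 44.7%).

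The DMSO groups were compared between the times, in cells kept in low serum. CCL3L3 (1.34 ± 0.07, adjusted p = 7.06e-11), CCL3 (0.96), CCL3L1 (0.85), SCARNA18 (0.80) and EGR1 (0.74) rose from 6 h to 12 h. HSPA6 (-0.90 ± 0.07, adjusted p = 1.02e-07), RBM3 (-0.78), HSPA1B (-0.76), CENPE (-0.73) and DNAJB1 (-0.65) fell. Under median centring RBM3 (-0.70, adjusted p = 0.124), HSPA1B (-0.64, adjusted p = 0.142), CENPE (-0.67, adjusted p = 0.131) and DNAJB1 (-0.57, adjusted p = 0.476) did not pass, and HSPA1B did not pass without DMSO 6 h replicate 1 (0.0546) or DMSO 12 h replicate 2 (0.0628). Heat shock genes fell as a list (6 of 16 fell and none rose, 10 fell adjusted over the list alone; adjusted p = 9.23e-13, and adjusted p = 0.00458 with an estimated correlation).

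ATF4 response genes (4 of 28 rose, 11 adjusted over the list alone; adjusted p = 6.17e-11, and adjusted p = 0.00945 with an estimated correlation) and cholesterol synthesis genes (3 of 19, 8 adjusted over the list alone; adjusted p = 3.83e-10, and adjusted p = 0.0158) were higher in DMSO at 12 h. FGF and MAPK response genes were higher too, with 2 of 21 rising (6 adjusted over the list alone). Their list gave adjusted p = 2.65e-05, and adjusted p = 0.0158 with an estimated correlation. Lysosome genes (list adjusted p = 0.000461, estimated 0.0373) and endoplasmic reticulum chaperones (0.000973, estimated 0.0479) were called upward, and mitotic genes (0.000668, estimated 0.0475) and genes activated by MYC (0.00303, estimated 0.0487) downward. Plasma cell genes (0.00166), genes promoting apoptosis (0.0254) and genes MYC represses (0.0311) were called upward with the preset correlation only, with estimated values of adjusted p = 0.0772, 0.0772 and 0.0831. By limma 80 genes changed over time in DMSO, 50 higher and 30 lower, and 2021 had an unadjusted p under 0.05. Under median centring 13 were higher and 1 lower. Another split of these 6 arrays called 82 genes, the fit on these arrays alone called 15 and an unmoderated test 1. The count was 45, 38 and 20 without DMSO 6 h replicate 1, 2 or 3, and 21 and 122 without DMSO 12 h replicate 2 or 3. Without DMSO 12 h replicate 1, 80 genes were higher.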

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

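Of the tests in this part, those of array brightness and of dim DMSO arrays on the counts, and that of heat shock genes in DMSO, were chosen after the results were seen, and the counts of other splits were chosen before. Of 129 genes named for 6 h, 12 h or the difference between the times, 87 had a response that differed between the times in the limma test of that difference. Some were named for that difference, so the choice raises this share. Over all genes it was 10.4%. The values below are log2 differences between responses, 12 h minus 6 h, each on 3 arrays per group; gained and lost are relative to DMSO, whose own level can have moved.

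Stress genes differed in both directions. Among chaperones, BAG3 (0.94), HSPA6 (0.89), HSPA1A (1.52), CRYAB (0.65), HSPA1B (0.60) and DNAJB1 (0.57) gained and HSPB1 lost (-0.33), and the heat shock list had a median of 0.34 (0.49 under median centring). Of 9 metallothionein genes 5 lost and none gained, with MT2A at -0.85, MT1G at -0.74, MT1E at -0.66, MT1H at -0.92 and a list median of -0.64 (-0.37 under median centring). The metallothionein call by camera was lost with an estimated correlation (adjusted p = 0.0565). In limma, MT2A and MT1G did not pass under median centring (adjusted p = 0.229 and 0.496). HSPA1A, CRYAB and MT1H lay below background in DMSO at both times, and with these levels raised to background the differences were 1.49, 0.61 and -0.91. Endoplasmic reticulum genes PDIA6 (-0.83), EDEM1 (-0.53) and CRELD2 (-0.52) lost and DNAJB9 (0.38) gained, with a list median of -0.14 (-0.06 under median centring). The redox genes PRDX3 (-0.81) and TXNRD1 (-0.73) lost and GLRX2 gained (0.47). SLC7A5, an amino acid transporter, was at -0.68. Of 22 interferon genes 4 gained and none lost (IFI6 1.00, IFIT2 0.55 and OASL 0.46 among them), with a list median of 0.12 (0.16 under median centring). The interferon call by camera was lost with an estimated correlation (adjusted p = 0.211).

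Growth and replication genes differed as well. RRM2 (-1.43), UHRF1 (-0.93), E2F2 (-0.80) and MCM7 (-0.62) lost and GINS2 gained (0.61), with a replication list median of -0.16 that was -0.02 under median centring. CENPE (1.02), HMMR (0.62), TTK (0.47) and DLGAP5 (0.46) gained, with a mitosis list median of 0.10 (0.30 under median centring), and XRCC2 (1.28), of DNA repair, gained. MYC (-0.93), IRF4 (-0.74), PRDM1 (-0.68), NFKB1 (-0.53), BACH2 (-0.43), SDC1 (-0.42) and CCND2 (-0.42) lost, as did BCL2 (-0.66) and BIRC5 (-0.48), whereas HRK (0.57) and PMAIP1 (0.50) gained. TP53INP1 (-0.77) and SESN1 (-0.43), p53 targets, lost, although of 19 p53 targets 3 gained and 4 lost, with a list median of -0.01 (0.006 under median centring). NDRG1 (-0.96) and CDKN1B (-0.58) lost, with a median of -0.18 for genes MYC represses (-0.17 under median centring). EGR1 (-1.39), SPRY1 (-0.92) and PDGFRB (-0.38) lost and IL17RD gained (0.61), with a median of -0.15 for FGF and MAPK response genes (-0.12 under median centring).

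Named genes of metabolism differed too. SQLE (-1.08), INSIG1 (-0.98), HMGCS1 (-0.60) and LSS (-0.47) lost and CYP51A1 gained (0.64), with a cholesterol list median of -0.11 (-0.06 under median centring), and SCD (-0.82), FASN (-0.78) and ACLY (-0.74) lost. PGAM1 (-1.24), PFKFB3 (-0.80), HK2 (-0.68) and PGK1 (-0.59) lost and BNIP3 gained (0.36), with a hypoxia list median of -0.10 (0.01 under median centring). SDHA (-0.62) and ATP5F1A (-0.58) lost, although of 38 oxidative phosphorylation genes 3 gained and 2 lost, with a list median of 0.09 (0.29 under median centring). MAT2A (-0.52) lost, as did ULK1 (-0.78), PSMC4 (-1.25) and PSMD2 (-0.56), while MCOLN1 (0.58) and RPL14 (1.14) gained.

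RNA genes and others completed the set. RN7SK (1.77), RNU6-1 (1.24), TRA2A (1.51), TRA2B (0.71) and SNORD104 (0.63) gained, and SNORD14C (-1.48), XPOT (-1.41), HNRNPA0 (-0.84) and MIAT (-0.80) lost. RIMBP3 (2.06) and ID1 (1.61) gained, and CCL3 (-1.21), CCL3L1 (-1.12), MEF2D (-1.15) and SUN2 (-0.71) lost.

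Chance was examined with other splits. At 6 h 1 of the 10 splits of the 6 arrays, the real one, gave as many genes as the real one (2619, the highest other 0), and at 12 h 1 of 10 did (5784, the highest other 0). Over time in DMSO 2 of 10 gave as many (80, the highest other 82). The 10 splits are too few for a share under 0.05. Splits that mix the groups also place any real difference within groups, which widens the spread and lowers the count. The highest other of 0 is therefore no measure of chance. For the difference between the times, 5 of 100 drawn reassignments of time within treatment (of 200 possible) gave as many genes as the real one (2089, the highest other 2899), so chance was not excluded by this count. The draw included reassignments that keep the real NSC12 times. These can reach the real count whenever NSC12 arrays differ between the times, so the count could not decide. As a fact seen afterwards, those 5 were among the 6 drawn with the real NSC12 times, and the 94 others reached at most 3 genes. Those 94 mix the NSC12 times within groups, which widens the spread where NSC12 arrays differ. Their low counts therefore do not speak to chance either.

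More genes changed at 12 h than at 6 h, with a ratio of the counts of 2.21. Were uneven array brightness the cause, a brightness covariate would bring the ratio down, but it was 2.32. Without the dimmest array of each DMSO group it was 2.28. The second value argues against dim DMSO arrays as the source. The slope of the covariate comes from arrays within groups. All NSC12 arrays at 6 h (378.2 to 497.1) were dimmer than those at 12 h (547.9 to 617.7). Brightness that goes with time in NSC12 arrays therefore cannot be excluded. A longer exposure to NSC12, which the design names, stays open and was not tested apart from array handling, since no batch information was available.

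The heat shock list rose more at 12 h than at 6 h, but its level in DMSO fell between the times (median -0.24, bootstrap interval -0.343 to -0.0421). In NSC12 arrays the median change between the times was 0.0255, with an interval of -0.0775 to 0.149 that spans 0. For the list median, the fall in DMSO may therefore be the whole cause. At that level a further rise in NSC12 and this fall cannot be told apart. HSPA1A and CRYAB, below background in DMSO at both times, rose in NSC12 arrays by 1.492 and 0.605 between the times. Their gains were therefore not only a fall in DMSO. BAG3 in NSC12 arrays was at 11.34 to 11.574 at 6 h and 11.757 to 12.004 at 12 h. HSPA6 (13.935 to 13.998, then 13.87 to 13.992) and DNAJB1 (13.999 to 14.086, then 13.938 to 13.987) did not rise in NSC12. Both lay near the top of the scale, where a rise may be compressed. For cholesterol, endoplasmic reticulum and FGF and MAPK response genes the DMSO medians rose by 0.20, 0.09 and 0.09 between the times. A change in DMSO therefore stays open as the source of their losses and was not tested.

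Probes to which the platform annotation gives no single gene symbol, left out of the comparisons of genes, also carried signal. Of 17208 such probes, 673 changed at 6 h (301 higher, 372 lower) and 1785 at 12 h (1050 higher, 735 lower). These are 3.91% and 10.4%, against 8.99% and 23% of probes with a symbol.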

How the results depend on the processing

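The alternatives added after the data were seen are normexp correction, cyclic loess, the brightness covariate and leaving out the dimmest array of each DMSO group. Apart from leaving out each array in turn, named genes kept their side of the threshold in 1781 combinations of result and alternative. They lost the call in 53, gained it in 1 and reversed in 1, with the dimmest-array setting counted here. That reversal was HSPE1 at 12 h, at 0.16 (adjusted p = 0.153) with the mean of all probes. The 1781 include genes past the threshold in neither setting, whatever their sign. Named genes were followed under median centring, the mean of probes, the added constant, no intensity trend, the replicate block and the alternatives named above. They were not followed under the other alternatives, such as the unmoderated test. For lists, 171 combinations kept the call and 49 lost it. List calls were tested again among genes above background and with the mean of probes, array weights and the replicate block. An estimated correlation, fry and the alternatives added after the data were seen were the others. List calls were not tested under median centring, where only list medians are given. The cause was not tested for any of these changes of call unless stated.

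Median centring in place of quantile normalization called 1469 genes at 6 h, 275 of them higher, and at 12 h 1484 higher. For the difference between the times it called 363 (277 higher and 86 lower), and in DMSO over time 14 (13 higher and 1 lower). The median of all genes moved by at most 0.03 under any scaling. Requiring at least a 2-fold change, which can only lower a count, left 118 genes at 6 h (80 higher, 38 lower), 335 at 12 h (142 and 193), 65 for the difference (37 and 28) and 1 in DMSO (1 and 0). Testing every probe on its own, over more features, called 8709 probes at 12 h (4238 higher) and 42 in DMSO (28 and 14).

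An unmoderated two-group test called 918 genes at 6 h (386 and 532), 3685 at 12 h (1651 higher) and 1 in DMSO (0 and 1). Array weights called 304 genes in DMSO (167 and 137), and the fit on only the 6 arrays compared called 15 (9 and 6). Leaving out the dimmest array of each DMSO group, which leaves fewer samples, gave 38 in DMSO (27 and 11), and cyclic loess gave 16 lower. With the replicate block the counts were 2504 at 6 h, 5695 at 12 h, 1992 for the difference and 54 in DMSO, of which 18 lower. Samples of the same number did not pair: with group means removed, their correlations were 0.081 to 0.094 at 6 h and -0.166 to 0.066 at 12 h, and the best match had the same number in 14 of 36 cases.

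Of the list calls, 22 in all, 9 were made among genes above background, 5 with an estimated correlation and 49 with fry, which asks only whether a list's genes move.

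Without 1 array, with fewer samples, counts ranged at 6 h from 1980 to 2203 (higher 850 to 918, lower 1130 to 1294) and at 12 h from 5108 to 5533 (2382 to 2664, 2684 to 2967). For the difference they ranged from 1541 to 2160 (649 to 995, 892 to 1182), and list calls from 17 to 25. In DMSO over time they ranged from 20 to 122 (12 to 80, 8 to 53): 45, 38 and 20 without DMSO 6 h replicate 1, 2 or 3, 21 and 122 without DMSO 12 h replicate 2 or 3, and 80 higher without DMSO 12 h replicate 1. Named genes lost their call in 32 combinations and kept their side of the threshold in 1444, which include genes past it in neither fit. Lists lost the call in 18 and kept it in 246.

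Quantile normalization as an alternative was not run, since it was already the step used here on the deposited values. Signal over background limits dim genes, whose folds are understated by the background left in the values.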

Other observations

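Of the tests in this part, those of S phase and of tailed forms were chosen after the result was seen, as were the RNA classes; the tests of array brightness and of small nucleolar RNAs were written before their results were seen. Histone genes and spliceosomal U RNAs, whose transcripts carry no poly(A) tail, rose after NSC12. Of 69 replication-dependent histone genes, 46 of them above background, 40 rose and 1 fell at 6 h, and 43 rose and 2 fell at 12 h. As with the U1 RNAs, probes of similar histone genes may share signal, which was not tested. Counts and tests of these classes may therefore not be over separate measurements. H2AC20 rose by 1.94 and 1.88, and H1-2 by 0.84 and 0.92. Of 10 spliceosomal U RNAs, 9 rose at 6 h and 10 at 12 h, with none lower. Of 12 RNA polymerase III transcripts, 6 rose and none fell at 6 h, and 10 rose and 1 fell at 12 h; RNU6-1 rose by 0.74 and 1.98, and RN7SK rose 2.82-fold at 6 h and 9.6-fold at 12 h.

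Splicing factors fell over the same times: of 30, 14 fell and 1 rose at 6 h, and 15 fell and 4 rose at 12 h, with SRSF1 at -1.32 and -1.43 and HNRNPA0 at -1.12 and -1.96. With an estimated correlation, adjusted over 15 tests, limma's camera gave adjusted p = 0.000153 and 0.000656 for histones, 0.0018 and 0.00393 for U RNAs, 0.0681 and 0.0121 for polymerase III transcripts, and 0.00413 and 0.0126 for splicing factors at 6 h and 12 h. Small nucleolar RNAs, of which 45 of 279 rose and 21 fell at 6 h and 69 rose and 23 fell at 12 h, gave 0.0743 and 0.0681 in this test and were called upward with the preset correlation (adjusted p = 0.00116 and 0.000674). SNORA61 (-1.74) and SNORD104 (-1.55) were among the largest falls at 6 h.

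Technical explanations of the rise of histone genes and U RNAs were weighed. With array brightness as a covariate the 6 h median of histone genes above background was 0.89 (bootstrap interval 0.502 to 1.11), against 0.865 without, which argues against brightness for histones. More cells entering S phase would raise replication genes, whose 12 h median was -0.12 (-0.413 to 0.0956) against 0.887 for histones, which argues against more entry. The replication median was already known when this test was chosen. It cannot speak to cells held within S phase. More tailed forms of these RNAs, rather than more RNA, may explain the rise, such as the U RNA median of 1.72 at 6 h, and stay open, since the table holds no measure of tails.

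The hypothesis that small nucleolar RNAs follow the gene whose span holds them was tested across 103 of 136 above background. Their 12 h changes gave rho = 0.00779 (permutation p = 0.94, two-sided, 100000 resamples) and r = -0.0539, so it was not borne out; genes are not independent replicates.

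Further lists were not called at 12 h. Of 19 p53 targets, 4 rose and 5 fell (5 and 5 adjusted over the list alone; list adjusted p = 0.991, median 0.08, 0.03 under median centring, mean -0.04), with TP53INP1 at -1.06 and SESN1 at -0.72. Of 18 DNA repair genes, 3 rose and 4 fell (7 and 4 adjusted over the list alone; list adjusted p = 0.654), with XRCC2 at 0.98 and ATM at -0.64. Of 21 lysosome and autophagy genes, 2 rose and 6 fell (the same adjusted over the list alone; 0.791, median 0.03, -0.03 under median centring, mean -0.06), with ULK1 at -1.11 and MCOLN1 at 0.71. Of 27 proteasome subunits, 7 rose and 9 fell (the same adjusted over the list alone; 0.89, median 0.03, 0.21 under median centring, mean -0.07), with PSMD2 at -0.84 and PSMC4 at -0.69, whose other probes (-0.32, -0.27) did not pass and whose mean of probes did not either (-0.42, adjusted p = 0.0855). Of 10 cholesterol efflux genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone; 0.134), with NPC1 at -1.01 and MYLIP at 0.73.

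Among metabolic and signalling lists, 4 of 23 hypoxia and glycolysis genes rose and 10 fell at 12 h (4 and 11 adjusted over the list alone; list adjusted p = 0.216), with HK2 at -0.69, its second probe at -0.07, and PGK1 at -0.65. Of 14 antioxidant enzymes, 6 rose and 2 fell (6 and 3 adjusted over the list alone; 0.282), with PRDX3 at -0.76 and GLRX2 at 0.63, its second probe at 0.09. Of 19 NF-kB targets, 3 rose and 3 fell (the same adjusted over the list alone; 0.991), with NFKB1 at -0.67; the test pointed up where the median (-0.002, and -0.02 under median centring) and mean (-0.02) were below 0. Of 14 FGF receptors, ligands and adaptors, 2 rose and 2 fell (the same adjusted over the list alone; 0.944, median 0.01, -0.01 under median centring, mean -0.03), with GRB2 at -0.71 and FGF9 at 0.42. FGF9 lost its call under median centring (0.29, adjusted p = 0.176), as the mean of probes (0.23, adjusted p = 0.0847), without the dimmest array of each DMSO group (0.23, adjusted p = 0.152) and without DMSO 12 h replicate 1 (0.23, adjusted p = 0.223), DMSO 12 h replicate 2 (0.0741), NSC12 12 h replicate 2 (0.0799) or NSC12 12 h replicate 3 (0.0956).

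Of 10 genes MYC represses, 2 rose and 5 fell at 12 h (the same adjusted over the list alone; list adjusted p = 0.179), with NDRG1 at -1.13 and CDKN2B at -0.77. Of 9 genes raised by myeloma translocations, CCND2 (-0.79), ITGB7 (-0.52) and MAF fell (3 adjusted over the list alone; 0.304), ITGB7 not under median centring (-0.33, adjusted p = 0.0851). Of 44 ribosomal protein genes, 9 rose and 2 fell (9 and 1 adjusted over the list alone; 0.132), with RPL14 at 1.49. At 6 h none of these lists but the ribosomal one was called. Other lists not called at 6 h were replication (2 rose, 5 fell), mitosis (0 and 2), plasma cell (1 and 3), interferon (1 and 0), endoplasmic reticulum chaperones (1 and 0) and oxidative phosphorylation (2 and 3; median 0.005, -0.04 under median centring, mean -0.01), with adjusted p from 0.444 to 0.962.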
